A study of Mus musculus with 20 samples.

How the data were processed

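Polyadenylated RNA was sequenced from 20 libraries of cultured colon fibroblasts of C57BL6/J mice, in 5 groups of 4 libraries each. The groups were untreated fibroblasts and fibroblasts kept for 24 h in medium conditioned by APTK organoids, by APTKA organoids, or in either medium of an irradiated arm (5 fractions of 2 Gy). APTK and APTKA are the labels' names of organoid lines, which the labels do not expand. The labels do not say whether the organoids or the fibroblasts were irradiated. They also hold no untreated group with irradiation and no group given unconditioned organoid medium. Libraries are named here by group and by the labels' replicate number, I to IV. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

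The deposited values were whole-number read counts per gene, not normalised. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.5.2a, featureCounts 1.5.0-p1 and the genome build mm10. The annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. Each table listed 47729 Ensembl gene identifiers, of which 47224 were matched to a symbol and 505 were not. Reads of near-identical copies can be split or dropped by such counting. Values of histone, interferon-inducible, guanylate-binding, major histocompatibility and serum amyloid family members, and of Gapdh with its pseudogenes, are therefore uncertain. Of 283 genes named by the rule given in this section, 78 shared exon sequence with another annotated gene, 71 of them with a gene on the opposite strand. Among these are Rgs16, Spp1, Cxcl10, Timp3, Bnip3, Pdgfra, Cdkn1a, Ackr4, Pi15, Plk3, Mfap4, Lrrc17, Eln, Dact1 and Nrg1. Without a stated strand setting, reads in the shared parts cannot be told from those of an overlapping gene on the opposite strand. Spp1 overlaps Gm42793, and Pdgfra Mir7025 beside other genes, on the same strand, where a strand setting would not help.

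Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM scaling, robust dispersion estimates and the default expression filter by group, which left 14820 genes. A single fit with 5 group means over all 20 libraries shared the estimate of the spread (15 residual degrees of freedom). Adjusted p-values follow Benjamini and Hochberg over the genes tested, with a false discovery rate of 5%. Standard errors (SE) are the absolute log2 fold change over the square root of the F statistic. CPM values were computed from the deposited counts with TMM-scaled library totals and are given as mean ± SD over n = 4 libraries. Folds against a floor and ratios of low counts used the same scaled totals, while shares of counts, CPM said to be of unscaled totals and the filter of 5 CPM used unscaled ones. Principal components used log2 CPM with a prior count of 2. Coordinates are those of the mm10 assembly, counted from 1.

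There were 7 comparisons. Each medium was compared with untreated fibroblasts, APTKA medium with APTK medium, each irradiated medium with its counterpart without irradiation, and the irradiated media with each other. The last comparison tested the difference between the irradiation effects in the 2 media. The design, the tests, the alternatives, 26 gene lists, 11 lists of cell type markers and the rule for naming genes were set before the data were examined. In each comparison the rule took the 8 largest rises and the 8 largest falls among genes past the 5% threshold whose 4 libraries of each group did not overlap. Such genes also had a mean log2 CPM (with an offset of 0.5) of at least 2, and predicted or unnamed genes were left out. For the difference of irradiation effects the 5 largest and 5 smallest differences were taken. The rule also took up to 4 members of each list that passed the threshold, and 20 fixed genes whatever they did. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and the self-contained test fry, were run beside it.

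The library totals lay between 17.3 and 31.6 M counts. Where all libraries of a group were at 0, a fold is a lower bound set against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only, since reads were not marked by molecule. No replicate pair agreed within counting noise (chi-square per degree of freedom 4.79 to 88.2), so each library was counted once. On simulated counts with 50 genes changed per fold size, the test recovered 32% of genes changed 1.25-fold, 58% of those changed 1.5-fold and 88% of those changed 2-fold in the comparison of APTKA medium with untreated fibroblasts (6.80% false calls). For irradiated against plain APTKA medium the shares were 36%, 68% and 88% (4.67%), for irradiated against plain APTK medium 36%, 50% and 84% (4.96%), and for the difference of irradiation effects 6%, 54% and 78% (5.83%). For APTKA medium against untreated the simulation gave 147 calls, where the data gave 9096. The adjusted threshold is more lenient when more genes change, so the shares recovered may be too low for that comparison. The simulation gave all groups the same spread per gene. Replicate pairs of irradiated APTK libraries differed more (chi-square per degree of freedom 17.1 to 88.2) than those of APTK libraries (6.02 to 13.1). Untreated pairs gave 32.8 to 41.6 with untreated I and 9.78 to 17.4 without it. The measure kept loci that collect ribosomal RNA reads, which took 1.67% of counts in untreated I and 0.0183 to 3.48% in irradiated APTK libraries. What these loci add to it was not tested. The shares recovered may therefore not hold for comparisons with irradiated APTK medium.

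Alternatives were RLE and upper quartile scaling, no filter and a stricter filter of 5 CPM in 4 libraries, only the compared groups in the fit, the replicate number as a block, limma-voom, DESeq2 1.42.0, and each library left out in turn. Runs without the 2 libraries of lowest total, and without 6 loci that collect ribosomal or satellite-like reads, were added after seeing the data, as were list tests with an estimated correlation for left-out libraries. Each run without a library applied the expression filter anew, so the genes and list members tested could differ from the main fit. Without irradiated APTK IV, 15037 genes were tested.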

Results

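The series concerned inflammatory fibroblasts and resistance to neoadjuvant therapy in rectal cancer. Gene expression was measured by RNA-seq in cultured mouse colon fibroblasts, with 4 libraries in each of 5 groups: untreated, APTK medium, APTKA medium, irradiated APTK medium and irradiated APTKA medium. The mean total was 26.4 ± 1.83 M counts in untreated, 26 ± 1.35 with APTK medium, 25.1 ± 3.24 with APTKA medium, 23.1 ± 5.60 with irradiated APTK medium and 27.9 ± 2.67 with irradiated APTKA medium (SD, n = 4 each). Within the irradiated APTK group the totals were 19.6 (I), 17.3 (II), 29.2 (III) and 26.3 M counts (IV). The conditioning organoid line separated the libraries on the first principal component (56.4% of the variance), where the 8 APTKA libraries lay between 46.7 and 52.7 and the other 12 between -37.1 and -29.2. Untreated libraries stood apart on the second (16.1%), at -40.6 to -37.6, against 17.8 to 24.6 for the APTK groups. Plain and irradiated APTK libraries overlapped on the second component but not on the first (-37.1 to -34.4 and -34.3 to -29.2). Plain and irradiated APTKA libraries overlapped on the first but not on the second (0.552 to 3.16 and -1.47 to 0.303).

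**Figure D1:**
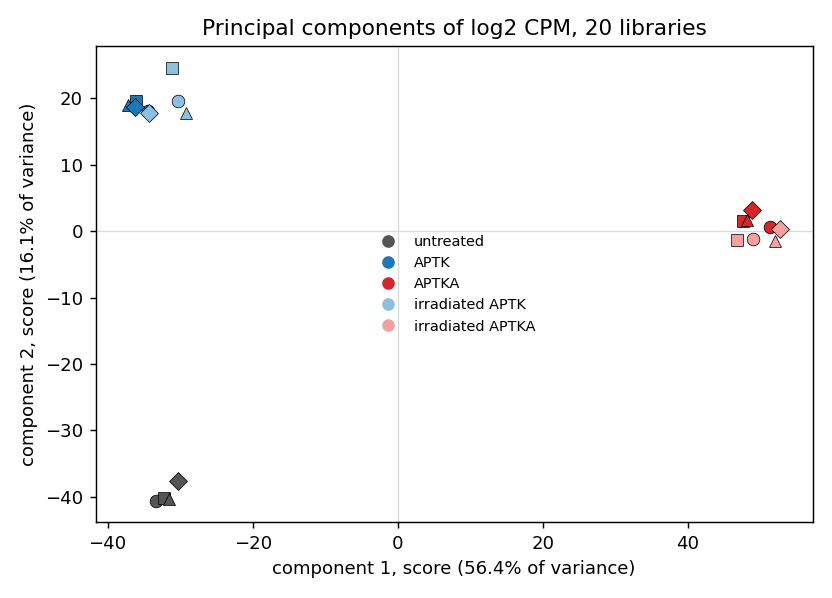
Scores of the 20 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis and a colour per group. The APTKA libraries lie at 46.7 to 52.7 on the first component and the untreated libraries at -40.6 to -37.6 on the second.

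The first comparison asked how medium of APTKA organoids changes the fibroblasts. Inflammatory mediator genes (21 of 25) and NF-kB feedback and target genes (16 of 20) rose with APTKA medium over untreated fibroblasts. Cxcl1, a neutrophil attractant (ENSMUSG00000029380, chromosome 5, 90891241 to 90893115), went from 3.24 ± 0.208 to 91.4 ± 7.83 CPM (SD, n = 4), a log2 fold change of 4.81 ± 0.121 SE (adjusted p = 9.12e-21). Cxcl5, another neutrophil attractant (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624), rose by 4.39 ± 0.140. Ccl2, which attracts monocytes (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), went from 40.6 ± 5.92 to 366.6 ± 40.7 CPM. Tnfaip3 and Nfkbia, feedback inhibitors of NF-kB, rose by 4.31 ± 0.0879 and 3.51 ± 0.0731. The largest rise under the naming rule was that of Stmn4, a stathmin-family microtubule regulator (ENSMUSG00000022044, chromosome 14, 66344296 to 66361680), from 0.904 ± 0.0782 to 58.6 ± 7.03 CPM (6.01 ± 0.131). The matrix protein gene Cilp (ENSMUSG00000042254, chromosome 9, 65265180 to 65280605) fell from 49.1 ± 2.42 to 0.415 ± 0.117 CPM (-6.88 ± 0.166).

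With edgeR's test, 9096 of 14820 genes differed between APTKA medium and untreated fibroblasts, 4668 higher and 4428 lower, and 1862 of them by at least 2-fold. Upper quartile scaling gave 4354 higher and 4741 lower. Ribosomal protein genes took 0.895 to 0.960% of counts with APTKA medium against 0.976 to 1.08% in untreated, and the 20 most abundant genes of a library 15.1 to 15.9% against 18.7 to 19.8%. The 4 libraries of a group did not overlap those of the other for 8036 of the called genes. Calls and overlap come from the same libraries, so such counts of called genes are no further evidence. The chance share of 2.86% holds over all genes tested and cannot be set against them. Rgs16, Bdkrb1 and Spp1 (osteopontin) were among the largest rises under the naming rule, at 3.82, 3.79 and 3.41. Rgs16 and Spp1 overlap other annotated genes. The largest falls under this rule included Trib3 (-4.81 ± 0.301) and Chac1 (-4.78 ± 0.221), both stress response genes, and Cldn1 (-4.17 ± 0.231), Col8a2 (-4.07 ± 0.172), G0s2 (-3.98 ± 0.217), Fmod (-3.85 ± 0.216) and Sema5a (-3.84 ± 0.168).

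Of 25 tested inflammatory fibroblast cytokines and mediators, 21 rose and 3 fell with APTKA medium, and the counts were the same when adjusted over the list alone (camera, Up, adjusted p = 1.40e-17). Saa3, an acute-phase protein gene, went from 0.0911 ± 0.0719 to 65.5 ± 32 CPM, and Il6 from 0.963 ± 0.147 to 3.16 ± 0.206 CPM. Cxcl2 had 1293 counts over the 4 APTKA libraries against 0 in untreated, at least 406-fold higher. Csf2 had 63 against 0, at least 19.8-fold higher, and Cxcl3 179 against 1 (ratio 169, interval 29.9 to 6698). Lif and Csf3, cytokine genes, rose by 1.51 ± 0.125 and 3.38 ± 0.387, and the alarmin Il33 fell (-3.17 ± 0.309). Of 20 NF-kB feedback and target genes 16 rose and 4 did not pass, also adjusted over the list alone (Up, 1.50e-13). Of 15 IL-1 family ligands, receptors and adaptors 4 rose and 6 fell (7 adjusted over the list alone), and the list did not pass (adjusted p = 0.835). Il1a rose by 3.38 ± 0.677 from a low level, Il1r1 fell (-0.35 ± 0.0828), and Il1rl1, the IL-33 receptor, rose by 2.22 ± 0.0928. Il1b and Il1rn were below the expression filter, at most 0.0550 CPM on average in any group.

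Of 28 collagens and extracellular matrix genes 24 fell with APTKA medium, also adjusted over the list alone (Down, adjusted p = 1.81e-10; adjusted p = 0.0657 with an estimated correlation), among them Eln (-2.20 ± 0.260), Fbln5 (-1.87 ± 0.0583) and Col1a1 (-0.75 ± 0.125). Among 22 matrix proteases and inhibitors 6 rose (7 adjusted over the list alone) and 12 fell (Down, 0.00516; adjusted p = 0.0657 with an estimated correlation). The proteases Mmp3 (4.13 ± 0.454), Mmp10 (3.11 ± 0.354) and Mmp9 (2.74 ± 0.184) rose while the inhibitor Timp3 fell (-2.86 ± 0.060), and the list's median of -0.36 and mean of 0.09 differed in sign. The integrated stress response and amino acid supply list had 22 of 24 members lower and 1 higher, also over the list alone (Down, 8.89e-37), including the amino acid transporters Slc7a5 (-3.70 ± 0.0869) and Slc7a11 (-3.58 ± 0.101). Of 22 endoplasmic reticulum chaperones 20 fell (21 adjusted over the list alone; Down, 1.36e-11), with Hspa5 going from 1354 ± 48.5 to 587.8 ± 32.2 CPM. Of 25 cholesterol synthesis and uptake genes 24 fell, also over the list alone (Down, 2.26e-09; adjusted p = 0.155 with an estimated correlation). NRF2 antioxidant genes had 3 higher and 14 lower of 20, also over the list alone (Down, 1.60e-06; adjusted p = 0.155 with an estimated correlation).

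Type I interferon-stimulated genes were lower with APTKA medium in 25 of 29 cases (26 adjusted over the list alone) and higher in 1 (Down, adjusted p = 0.00359; adjusted p = 0.698 with an estimated correlation). The member that rose was Cxcl10 (2.81 ± 0.273), a chemokine that overlaps Art3. Of 20 antigen presentation and interferon-gamma targets 2 rose and 12 fell, also over the list alone (Down, 0.00516; adjusted p = 0.260 with an estimated correlation). Glycolysis and hypoxia response genes had 17 higher and 4 lower of 26, also over the list alone (Up, 0.000134; adjusted p = 0.177 with an estimated correlation). The lactate exporter Slc16a3 rose by 2.59 ± 0.115. Of 28 DNA replication genes 19 rose and 1 fell, also over the list alone (Up, 0.00219; adjusted p = 0.361 with an estimated correlation). Of 17 quiescent and adventitial fibroblast genes 3 rose and 12 fell, also over the list alone (Down, 0.00673). Inflammatory, NF-kB, stress response, chaperone and quiescent lists also passed with an estimated correlation (adjusted p = 4.45e-05, 0.00393, 4.45e-05, 0.0096 and 0.0338).

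The other lists did not pass camera in this comparison. Of 30 p53 target genes 18 rose and 7 fell (8 adjusted over the list alone; adjusted p = 0.0644), and the list passed without APTKA III (0.0256) or APTKA IV (0.0409), though not with an estimated correlation (adjusted p = 0.408 and 0.492). Mdm2, the p53 ubiquitin ligase, went from 287.9 ± 25.2 to 515.3 ± 44.9 CPM and Cdkn1a, the cell cycle inhibitor p21, from 177.1 ± 17.6 to 272.6 ± 11.3 CPM, and Trp53 rose by 0.53 ± 0.112. Mitotic genes had 8 higher and 1 lower of 25 (6 higher adjusted over the list alone; 0.311), DNA repair and damage signalling genes 14 and 6 of 26 (0.335), and senescence-associated secreted factors and cell cycle inhibitors 12 and 12 of 25 (0.359). Mki67, a proliferation marker, was higher by 0.35 ± 0.144, a call lost without untreated II (0.36), III (0.24) or IV (0.36) or without APTKA II (0.37), III (0.26) or IV (0.31). Contractile myofibroblast genes had 7 higher (8 adjusted over the list alone) and 6 lower of 19 (0.636), with Acta2 lower (-0.38 ± 0.0741), and TGF-beta direct targets 6 and 7 of 18 (0.907). Tgfb1 itself was at -0.10 ± 0.110 (adjusted p = 0.426). Immediate early and MAPK feedback genes had 11 higher (12 adjusted over the list alone) and 9 lower of 22 (0.444), autocrine JAK-STAT3 targets 7 and 5 of 18 (0.359), and complement components 3 and 6 (7 adjusted over the list alone) of 11 (0.407). Niche Wnt, R-spondin and BMP factors had 9 and 9 of 21 (0.859), growth factors for epithelium 8 and 7 of 19 (0.495) and Wnt/beta-catenin targets 3 and 4 of 10 (0.859). Unless stated, these counts were the same adjusted over the list alone. Pdgfra and Cdkn2a were lower, at -0.36 ± 0.0862 and -0.57 ± 0.0946.

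**Figure D2:**
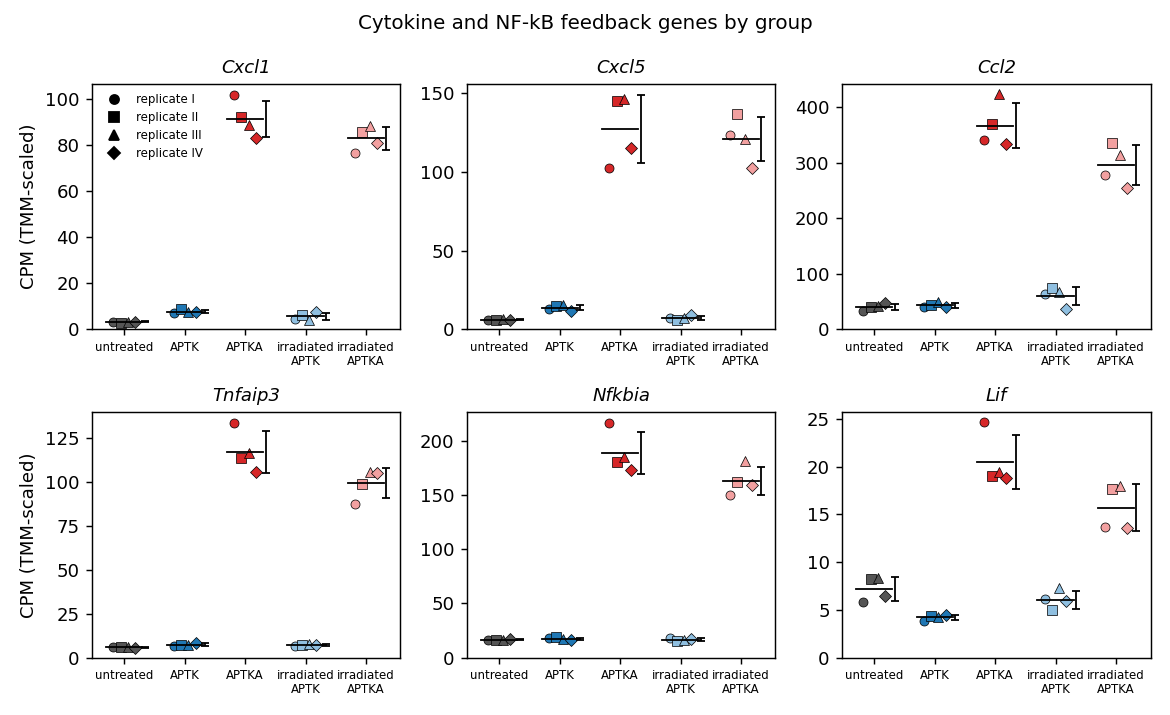
CPM of Cxcl1, Cxcl5, Ccl2, Tnfaip3, Nfkbia and Lif in each of the 20 libraries by group on linear axes from 0, with a marker shape per replicate number, a line at the group mean and a bar of 1 SD. Cxcl1 averages 91.4 CPM with APTKA medium and 82.9 CPM with irradiated APTKA medium, against 3.24 CPM in untreated fibroblasts and 7.72 CPM with APTK medium.

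Among markers of other cell types, those of pericytes and vascular smooth muscle had 7 of 9 lower and 1 higher with APTKA medium (camera over the marker lists, Down, adjusted p = 0.0018; adjusted p = 0.0409 with an estimated correlation). Epcam reached at most 0.105 CPM and Ptprc at most 0.195 CPM in any library. Among tested epithelial markers 2 of 5 rose and 1 fell (adjusted p = 0.869), and among endothelial markers 2 of 8 rose and 2 fell (0.961). Macrophage and monocyte markers had 2 higher and 2 lower of 4, adipocyte markers 1 and 2 of 3, mesothelial markers 1 and 1 of 2, and enteric glia and neuron markers 1 and 1 of 3. The neutrophil and mast cell marker tested rose, the lymphocyte marker fell, and 1 of 2 markers of interstitial cells of Cajal fell. The 13 fibroblast markers had 11 lower and 1 higher (Down, 0.0018, and adjusted p = 0.0409 with an estimated correlation), beside the falls of collagen genes given for this medium. Col1a1, Col1a2, Col3a1, Dcn and Lum are members of both lists, so these results are not independent.

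APTK medium was compared with untreated fibroblasts to describe the response to the other organoid line. Hypoxia and glycolysis genes rose (21 of 26) and p53 target genes fell (22 of 30). Slc16a3 (ENSMUSG00000025161, chromosome 11, 120948480 to 120960868) went from 16.0 ± 2.21 to 143.5 ± 3.19 CPM (SD, n = 4; log2 3.16 ± 0.116 SE, adjusted p = 1.72e-14). Pdgfra, which encodes platelet-derived growth factor receptor alpha (ENSMUSG00000029231, chromosome 5, 75152292 to 75198215), went from 81.4 ± 5.86 to 262.6 ± 6.54 CPM. Ptx3, a pattern recognition protein gene (ENSMUSG00000027832, chromosome 3, 66219910 to 66225805), fell from 66.5 ± 3.23 to 10.3 ± 1.12 CPM. Rsad2, an antiviral interferon-stimulated gene (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), went from 5.36 ± 1.10 to 26.4 ± 7.79 CPM.

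With APTK medium 6433 genes differed from untreated, 3099 higher and 3334 lower, 943 of them at least 2-fold, and groups did not overlap for 5615 called genes. Which direction held more genes turned with upper quartile scaling (3730 higher and 2898 lower) and without a filter (3262 and 3063). Mitochondrially encoded genes took 0.765 to 0.922% of counts with APTK medium against 0.538 to 0.671% in untreated, and ribosomal protein genes 1.11 to 1.29% against 0.976 to 1.08%. Mgarp (2.86 ± 0.131), Ms4a4d (2.56), Cck (2.55 ± 0.290), Cxcl10 (2.31 ± 0.283) and Pygl, glycogen phosphorylase (2.25 ± 0.0962), were among the largest rises under the naming rule. Limch1 (-2.49 ± 0.145), the stress response factor Atf3 (-2.25 ± 0.365), the guidance molecule Sema3c (-2.16 ± 0.179), Pi15 (-2.16 ± 0.206), Il1rl1 (-2.07 ± 0.123), Alcam (-2.05 ± 0.0868) and Dpt (-2.05) were among the largest falls under it. Of the 25 inflammatory genes 8 rose and 4 fell, also over the list alone (camera adjusted p = 0.369). Cxcl1 rose from 3.24 ± 0.208 to 7.72 ± 0.667 CPM and Cxcl5 by 1.19 ± 0.150 on the log2 scale, Lif fell (-0.76 ± 0.142), and Ccl2 was at 0.09 ± 0.177 (adjusted p = 0.711). Il6 was lower (-0.82 ± 0.264), a call lost without untreated III (-0.71) or APTK III (-0.57). NF-kB genes had 5 higher and 5 lower of 20 (0.881).

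Of 26 glycolysis and hypoxia genes 21 rose and 1 fell with APTK medium (22 and 2 adjusted over the list alone; Up, adjusted p = 7.91e-25), including Bnip3 (2.03 ± 0.094), while Ndrg1 fell (-1.15 ± 0.0918). Gapdh in this list shares sequence with many pseudogenes. Of 29 interferon-stimulated genes 24 rose, also over the list alone (Up, 1.34e-07; adjusted p = 0.514 with an estimated correlation). Of 30 p53 targets 22 fell and 2 rose (23 lower over the list alone; Down, 3.06e-09), with Mdm2 and Cdkn1a lower (-0.52 ± 0.0689 and -0.45 ± 0.0690). Trp53 was also lower (-0.35), a call lost without untreated II (-0.23) or APTK I (-0.28). Of 24 stress response and amino acid supply genes 19 fell and 2 rose (20 lower over the list alone; Down, 9.42e-09), and of 22 matrix proteases and inhibitors 15 fell and 1 rose (16 lower over the list alone; Down, 5.44e-06). Of 17 quiescent fibroblast genes 7 fell and 2 rose, also over the list alone (Down, 0.00213). NRF2 genes had 13 lower and 1 higher of 20 (14 and 2 over the list alone; Down, 0.000104; adjusted p = 0.363 with an estimated correlation). The glycolysis, p53, stress response, protease and quiescent lists also passed with an estimated correlation (adjusted p = 0.00369, 0.0249, 0.0249, 0.00899 and 0.0182).

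Some lists of the APTK comparison lost or gained the call when a single library was left out. Immediate early and MAPK feedback genes had 9 higher and 3 lower of 22 (4 lower over the list alone; Up, 0.0363; adjusted p = 0.282 with an estimated correlation), lost without untreated III (0.0591) or IV (0.0608). Etv4, a transcription factor induced by MAPK signalling, rose by 1.69 ± 0.156. DNA replication genes had 15 higher and 4 lower of 28, also over the list alone (Up, 0.0411; adjusted p = 0.735 with an estimated correlation), lost without untreated I (0.106), untreated II (0.0548) or APTK III (0.0510). Collagens and matrix genes had 2 higher and 9 lower of 28 (0.0527) and passed without untreated I (0.0409), untreated III (0.0415) or APTK IV (0.0354). Cholesterol genes had 8 higher and 4 lower of 25 (0.166) and passed without untreated IV (0.0147). With an estimated correlation the collagen list did not pass without these libraries (adjusted p = 0.785, 0.753 and 0.724), nor did the cholesterol list (adjusted p = 0.635). Col1a1, Acta2, Mki67, Tgfb1 and Mmp3 did not pass, at -0.11, -0.14, 0.26, -0.13 and -0.12. Acta2 passed without untreated II (-0.20).

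The 2 media shared their untreated controls. Of the called genes 1425 were higher and 1813 lower with both, against 976.1 and 996.2 for independent lists, and 1305 changed in opposite directions. Simulated unchanged groups with shared simulated controls gave 0.275 called genes per comparison on average. Their 0.025 shared calls are therefore no baseline for lists of this size. With the untreated libraries split between the comparisons, 981 to 1061 genes were higher and 1391 to 1479 lower with both, and 884 to 1100 opposite. Independent lists would give 650.3 to 749.9 higher and 704.7 to 786.3 lower there. Across genes, which are not independent replicates, the log2 fold changes had r = 0.39, and r = 0.320 to 0.345 with split controls. Simulated unchanged groups with shared simulated controls gave r = 0.496, above the observed value. No gene was changed there, so that r comes from the shared controls alone and is no baseline for r = 0.39. The covariance was 0.172, and 0.151 to 0.162 with split controls, against 0.0191 for simulated unchanged groups.

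APTKA medium was compared with APTK medium directly to separate the organoid lines. Inflammatory (21 of 25) and NF-kB genes (17 of 20) were higher with APTKA medium and stress response (21 of 24) and chaperone genes (21 of 22) lower. Stmn4 was at 58.6 ± 7.03 against 0.617 ± 0.288 CPM (SD, n = 4; log2 6.55 ± 0.139 SE). Mmp10, a stromelysin, was at 31.0 ± 7.06 against 1.28 ± 0.308 CPM (4.58 ± 0.411) and Il1rl1 at 45.8 ± 3.36 against 2.34 ± 0.286 CPM (4.29 ± 0.112). Trib3, a pseudokinase of the stress response (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032), was at 5.69 ± 0.658 against 93.3 ± 8.66 CPM. Pdgfra was at 63.2 ± 7.43 against 262.6 ± 6.54 CPM. Between these media 9324 genes differed, 4607 higher and 4717 lower with APTKA medium, 1756 at least 2-fold, and groups did not overlap for 8457 called genes. DESeq2 gave 4622 higher and 4618 lower, and a fit on only these groups 4849 and 4805. Mitochondrially encoded genes took 0.404 to 0.598% of counts with APTKA against 0.765 to 0.922% with APTK medium, ribosomal protein genes 0.895 to 0.960% against 1.11 to 1.29%, and the 20 most abundant genes 15.1 to 15.9% against 18.5 to 19.2%.

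Atf3 (4.08 ± 0.320), Tnfaip3 (4.00 ± 0.0854), Cxcl1 (3.56 ± 0.107), Mmp9 (3.54 ± 0.198) and Bdkrb1 (3.44) were among the largest differences towards APTKA medium under the naming rule. Cilp (-5.80 ± 0.173), the scavenging chemokine receptor Ackr4 (-4.81 ± 0.352), Abca8a (-4.57 ± 0.187), the interferon-inducible GTPase Iigp1 (-4.44 ± 0.350) and Cmpk2 (-3.99 ± 0.347) were among those towards APTK medium under this rule. Of 25 inflammatory genes 21 were higher and 3 lower, and of 20 NF-kB genes 17 higher and 1 lower, both also over the list alone (camera, Up, adjusted p = 1.05e-16 and 2.45e-15). Of 30 p53 targets 23 were higher and 3 lower, also over the list alone (Up, 3.26e-09), with Mdm2 at 1.36 ± 0.0697 and Cdkn1a at 1.07 ± 0.0693. Of 29 interferon-stimulated genes 28 were lower, also over the list alone, where 1 was higher (Down, 4.57e-10; adjusted p = 0.366 with an estimated correlation). Mx1 had 3 counts with APTKA medium against 370 with APTK medium (ratio 128, interval 43.4 to 622). Antigen presentation genes had 16 lower and 1 higher of 20 (17 lower over the list alone; Down, 0.000225; adjusted p = 0.155 with an estimated correlation).

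All 25 cholesterol genes were lower with APTKA than with APTK medium, also over the list alone (Down, 1.96e-13; adjusted p = 0.0908 with an estimated correlation). The stress response list had 21 of 24 lower and 1 higher and the chaperone list 21 of 22 lower, also over the lists alone (Down, 7.92e-22 and 2.53e-14). Collagens and matrix genes had 22 of 28 lower (23 over the list alone) and 2 higher (Down, 2.04e-07; adjusted p = 0.155 with an estimated correlation). Glycolysis genes had 15 lower and 3 higher of 26, also over the list alone (Down, 0.0248; adjusted p = 0.579 with an estimated correlation), and NRF2 genes 11 lower (12 over the list alone) and 5 higher of 20 (Down, 0.0202; adjusted p = 0.618 with an estimated correlation). The inflammatory, NF-kB, p53, stress response and chaperone calls held with an estimated correlation (adjusted p = 6.54e-05, 0.00229, 0.0369, 0.000601 and 0.00343). Fibroblast markers had 12 of 13 lower and 1 higher (Down, 4.11e-06, and adjusted p = 0.00608 with an estimated correlation), beside the lower collagen genes, with which they share Col1a1, Col1a2, Col3a1, Dcn and Lum. Pericyte markers had 7 of 9 lower and 1 higher (Down, 0.00118, and adjusted p = 0.0334 with an estimated correlation).

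**Figure D3:**
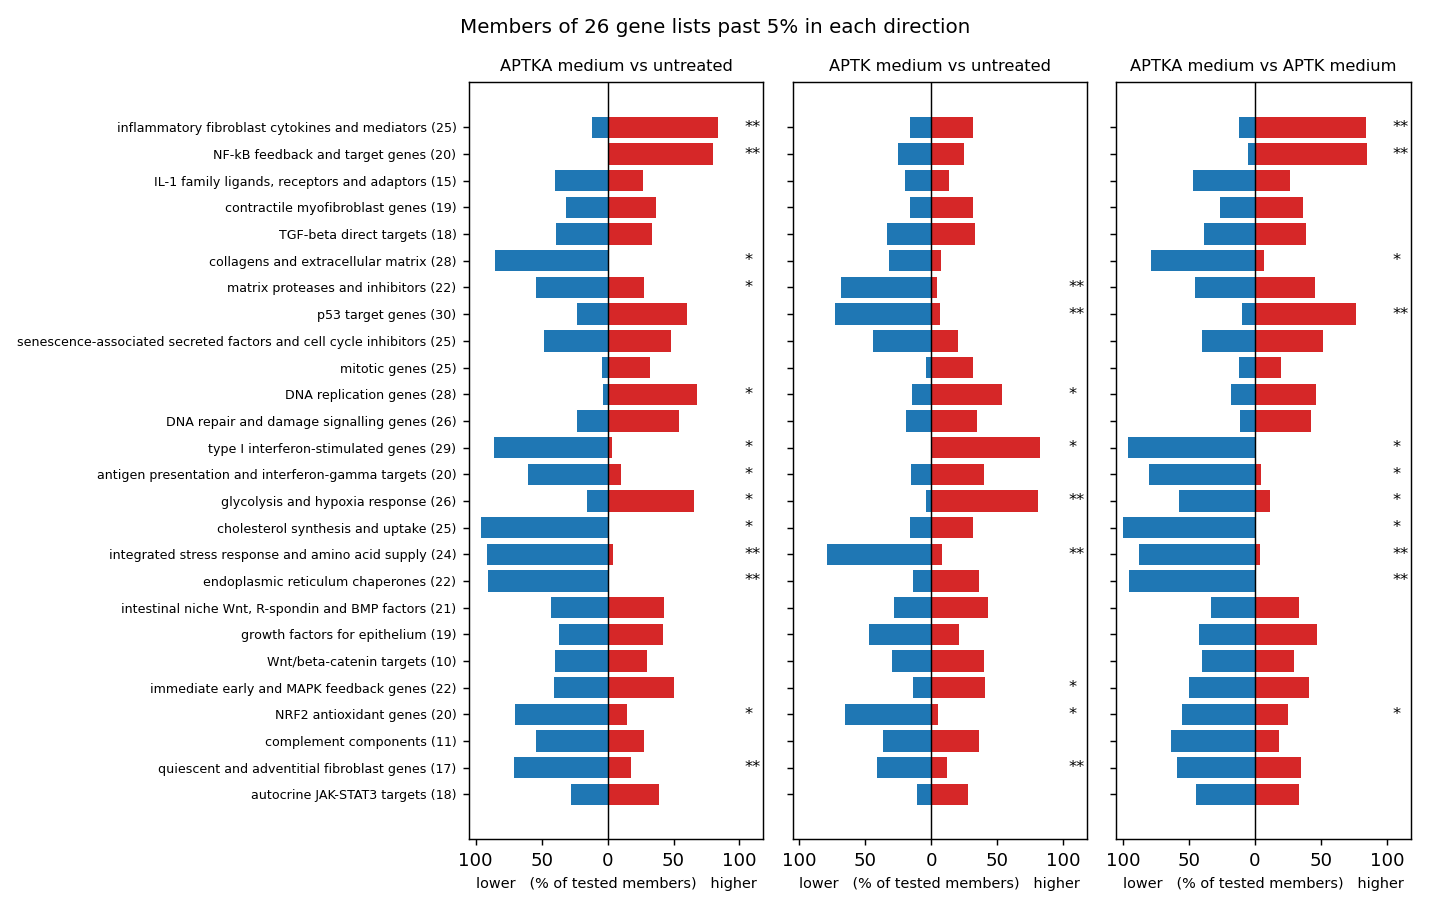
Share of the tested members of each of 26 gene lists, in percent, that were higher (bars to the right) or lower (bars to the left) in the comparisons of APTKA medium with untreated, APTK medium with untreated and APTKA with APTK medium, with tested members in parentheses. An asterisk marks a list past 5% in camera with the preset correlation and a pair of asterisks a list past it with an estimated correlation too. Of 29 interferon-stimulated genes, 24 were higher with APTK medium than untreated and 25 lower with APTKA medium.

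**Figure D4:**
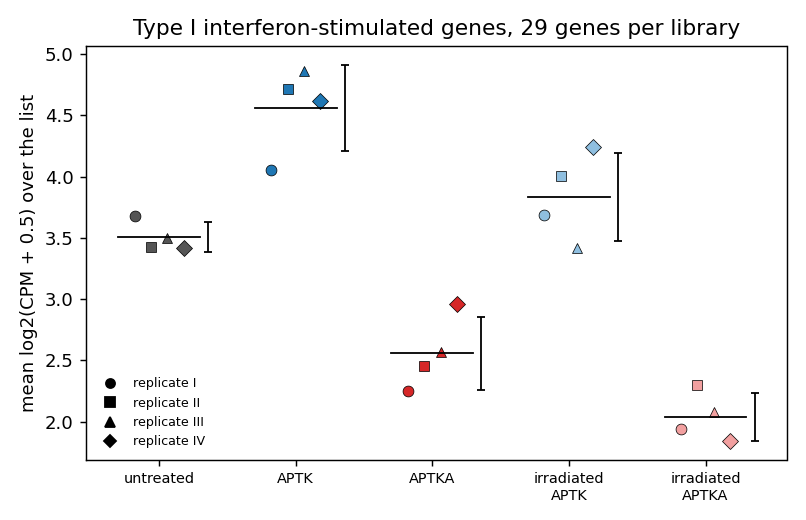
Mean log2(CPM + 0.5) over the 29 tested interferon-stimulated genes in each library by group, with a line at the group mean. The 4 APTK libraries lie between 4.05 and 4.86 and the 4 APTKA libraries between 2.25 and 2.96, with untreated libraries between 3.42 and 3.68.

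Irradiated APTKA medium was compared with APTKA medium to describe what irradiation added. Of 20 NRF2 antioxidant genes 5 rose and of 28 DNA replication genes 3 fell. Both lists passed camera with an estimated correlation (adjusted p = 0.0206 each), a call lost without APTKA I (adjusted p = 0.0514 each). Nqo1, a quinone reductase (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206), went from 28.2 ± 2.08 to 47.9 ± 3.51 CPM (SD, n = 4; log2 0.77 ± 0.0894 SE, adjusted p = 6.26e-05). Aldh1a3, a retinaldehyde dehydrogenase (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517), went from 69.8 ± 12.2 to 128.4 ± 13.2 CPM. Spry2, a feedback inhibitor of MAPK signalling (ENSMUSG00000022114, chromosome 14, 105891947 to 105896819), fell from 103.3 ± 3.95 to 60.9 ± 7.68 CPM (-0.76 ± 0.0865). Mcm2, a subunit of the replicative helicase, fell from 38.8 ± 1.52 to 27.4 ± 2.00 CPM.

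Between irradiated and plain APTKA medium 108 genes differed, 67 higher and 41 lower, 9 of them at least 2-fold (103 of the called genes without overlap of the groups). Upper quartile scaling gave 47 higher and 47 lower. Without a filter 316 genes differed, with DESeq2 307 and with only the compared groups in the fit 512. The count fell to 40 without APTKA II, 34 without APTKA III, 35 without APTKA IV, 37 without irradiated APTKA I, 44 without irradiated APTKA III and 56 without irradiated APTKA IV. Of the 16 genes named by size, 9 passed whichever library was left out: Aldh1a3, Nqo1, Gsta4 (0.68 ± 0.101), Lrrc4c (0.54 ± 0.0882), Gpr137b (0.52), Dact1 (0.51), Spry2, Gdf6 (-0.75 ± 0.103) and the histone gene Hist1h1b (-0.61 ± 0.113). The fixed genes did not pass: Cxcl1 was at -0.14 ± 0.0887 (adjusted p = 0.555), Ccl2 at -0.31 ± 0.165 (0.477), Cdkn1a at 0.01 ± 0.0681 (0.971) and Mdm2 at -0.15 ± 0.0683 (0.370).

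By list, 5 of 20 NRF2 genes rose with irradiated APTKA medium (12 adjusted over the list alone; camera, Up, adjusted p = 2.15e-18). Of 28 DNA replication genes 3 fell (18 lower over the list alone; Down, 2.82e-18) and of 25 mitotic genes 2 fell (12 lower over the list alone; Down, 1.76e-13). Immediate early and MAPK feedback genes had 2 of 22 lower (4 lower and 1 higher over the list alone; Down, 1.84e-05), and matrix proteases and inhibitors 3 of 22 higher (5 over the list alone; Up, 0.000317). These 5 lists also passed with an estimated correlation (adjusted p = 0.0206, 0.0206, 0.0444, 0.0206 and 0.0266). Without APTKA I none of the 5 did, with adjusted p = 0.0623 for MAPK feedback genes and 0.0514 for the other 4 lists. Proteases (0.0720) and MAPK feedback genes (0.0505) also lost this call without irradiated APTKA II, and mitotic genes without APTKA II (0.0609), III (0.0839) or IV (0.0575) or irradiated APTKA II (0.0720) or III (0.0723). Interferon-stimulated genes had 12 of 29 lower over the list alone (Down, 3.60e-18; adjusted p = 0.101 with an estimated correlation), inflammatory genes 6 lower and 1 higher of 25 (Down, 0.00460; adjusted p = 0.0834 with an estimated correlation) and NF-kB genes 4 lower of 20 (Down, 0.000418; adjusted p = 0.101 with an estimated correlation). In the p53 list camera gave Down (0.0187; adjusted p = 0.319 with an estimated correlation), lost without APTKA I (0.503).

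In all 18 of 26 lists passed with the preset correlation for irradiated against plain APTKA medium, 9 Up and 9 Down. The other lists with Down were DNA repair genes (4.74e-06) and antigen presentation genes (0.00909, lost without irradiated APTKA IV, 0.0585). The other lists with Up were collagens (0.000219), TGF-beta targets (0.000657), chaperones (0.000657), stress response genes (0.000906), glycolysis genes (0.00110), cholesterol genes (0.00400, lost without irradiated APTKA IV, 0.0813) and contractile genes (0.0335). The contractile call was lost without APTKA I (0.0518), APTKA II (0.136), irradiated APTKA III (0.0548) or irradiated APTKA IV (0.409). In this order the 9 lists had adjusted p = 0.0800, 0.251, 0.239, 0.0880, 0.150, 0.151, 0.239, 0.378 and 0.485 with an estimated correlation. Over the lists alone 3, 1, 3, 4, 2, 4, 3, 0 and 0 members passed in the direction of the list, and 1 glycolysis gene was lower. The senescence list (0.0678) passed without APTKA III (0.0125) or irradiated APTKA IV (0.0496), though not with an estimated correlation (adjusted p = 0.162 and 0.249).

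Irradiated APTK medium was compared with APTK medium in the same way. Nqo1 went from 44.9 ± 4.39 to 76.9 ± 9.24 CPM (SD, n = 4; log2 0.77 ± 0.0871 SE, adjusted p = 4.42e-05). Id1, an inhibitor of differentiation induced by BMP signalling (ENSMUSG00000042745, chromosome 2, 152736251 to 152737410), rose by 0.88 ± 0.142. Chac1, a glutathione-degrading enzyme of the stress response (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), fell from 30.6 ± 2.14 to 13.6 ± 5.47 CPM (-1.19 ± 0.170). Cxcl5 fell from 13.7 ± 1.63 to 7.38 ± 1.36 CPM (-0.88 ± 0.148). Sesn2, a stress-induced regulator of mTORC1, fell (-0.47 ± 0.0567).

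Here 205 genes differed, 81 higher and 124 lower, 23 at least 2-fold (144 of the called genes without overlap). With only the compared groups in the fit 10 genes differed, 6 higher and 4 lower, while 492 did without a filter and 439 with DESeq2. Without irradiated APTK I and II, the libraries of lowest total, 27 differed. All 4 irradiated APTK libraries had a higher mean correlation over genes with the plain APTK libraries (0.987 to 0.993) than with the others of their own group (0.986 to 0.990). On the line from the plain APTK mean (0) to the irradiated APTK mean (1), each without the library placed, the library labelled irradiated APTK IV lay at 0.193, plain libraries at 0.220 to 0.365 and irradiated APTK I to III at 0.569 to 0.702. In Spp1 replicate IV was at 10.6 CPM against 60.6 to 67.0 CPM in irradiated APTK I to III and 13.0 ± 1.80 CPM with APTK medium. In Chac1 it was at 13.7 CPM, within the 9.12 to 21.3 CPM of irradiated APTK I to III and below the 28.4 to 32.7 CPM of the APTK libraries. Without it 1271 genes differed, 693 higher and 578 lower, with all 205 among them. The count was 59 without APTK II, 32 without APTK III, 72 without APTK IV, 33 without irradiated APTK I, 122 without irradiated APTK II and 47 without irradiated APTK III. Mitochondrially encoded genes took 1.21%, 1.23%, 0.534% and 1.01% of counts in irradiated APTK I to IV, against 0.812 ± 0.0740% with APTK medium. Loci that collect ribosomal RNA reads took 3.48%, 0.0183%, 0.0396% and 2.32% in irradiated APTK I to IV, against 0.0920 ± 0.0565% with APTK medium and 1.67% in untreated I. On the third principal component (4.16% of the variance) irradiated APTK II lay at -40.8, and the other 19 libraries between -5.66 and 13.4. Of the 16 genes named by size 8 passed whichever library was left out: Id1, Nqo1, Tnfrsf21 (0.69 ± 0.108), Plk3 (0.61 ± 0.0950), Chac1, Cxcl5, Prss35 (-0.77 ± 0.137) and Mfap4 (-0.75 ± 0.116). Of the 20 fixed genes Cxcl5 passed, and without irradiated APTK IV also Cxcl1 (-0.66 ± 0.116), Ccl2 (0.66 ± 0.116), Lif (0.55) and Mmp3 (1.58).

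Interferon-stimulated genes had 7 of 29 lower with irradiated APTK medium (29 over the list alone; camera, Down, adjusted p = 6.13e-27; adjusted p = 0.0846 with an estimated correlation), and 24 lower without irradiated APTK IV. Bst2, an interferon-induced antiviral protein gene, was at 53.1 ± 13.2 CPM with APTK and 28.2 ± 3.61 CPM with irradiated APTK medium, a call lost without APTK II (-0.90), APTK III (-0.75) or irradiated APTK I (-0.89), II (-0.87) or III (-0.89). Antigen presentation genes had 3 of 20 lower (10 over the list alone; Down, 7.92e-09) and stress response genes 5 of 24 (10 over the list alone; Down, 3.11e-10). MAPK feedback genes had 3 of 22 higher (9 over the list alone; Up, 6.87e-09). These 3 lists also passed with an estimated correlation (adjusted p = 0.0384, 0.0307 and 0.00456), but not without irradiated APTK IV (adjusted p = 0.0718, 0.101 and 0.0593 with an estimated correlation). Antigen presentation genes also lost this call without APTK II (0.0744), III (0.0761) or IV (0.0513) or irradiated APTK I (0.0606), II (0.0807) or III (0.0922), and stress response genes without APTK IV (0.0513) or irradiated APTK III (0.0553). NRF2 genes had 1 of 20 higher (7 over the list alone; Up, 1.15e-07; adjusted p = 0.148 with an estimated correlation) and 8 without irradiated APTK IV. Cholesterol genes had 6 of 25 lower (7 over the list alone; Down, 7.92e-09; adjusted p = 0.177 with an estimated correlation) and glycolysis genes 4 of 26 (7 over the list alone; Down, 5.58e-07; adjusted p = 0.128 with an estimated correlation). Of 18 JAK-STAT3 targets 3 were lower (4 lower and 1 higher over the list alone; Down, 0.000271; adjusted p = 0.211 with an estimated correlation). TGF-beta targets had 1 of 18 higher (5 over the list alone; Up, 0.0238; adjusted p = 0.250 with an estimated correlation), lost without APTK I (0.0732), APTK III (0.0930), irradiated APTK I (0.0822) or irradiated APTK IV (0.0839). Matrix proteases had 3 higher and 1 lower of 22 (6 and 2 over the list alone; Up, 0.0320; adjusted p = 0.177 with an estimated correlation), lost without APTK I (0.0843), APTK IV (0.0587) or irradiated APTK I (0.0776), III (0.176) or IV (0.0514). These made 10 lists past the test, 4 Up and 6 Down. NF-kB and p53 lists did not pass (0.260 and 0.473). The senescence list (0.157) passed without irradiated APTK II (0.0340) or IV (0.0413) and the mitotic list (0.168) without irradiated APTK IV (0.0317). The DNA replication list (0.234) passed without irradiated APTK II (0.0159) and the complement list (0.168) without APTK II (0.0420). None of these 4 did so with an estimated correlation (adjusted p = 0.194 to 0.504).

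**Figure D5:**
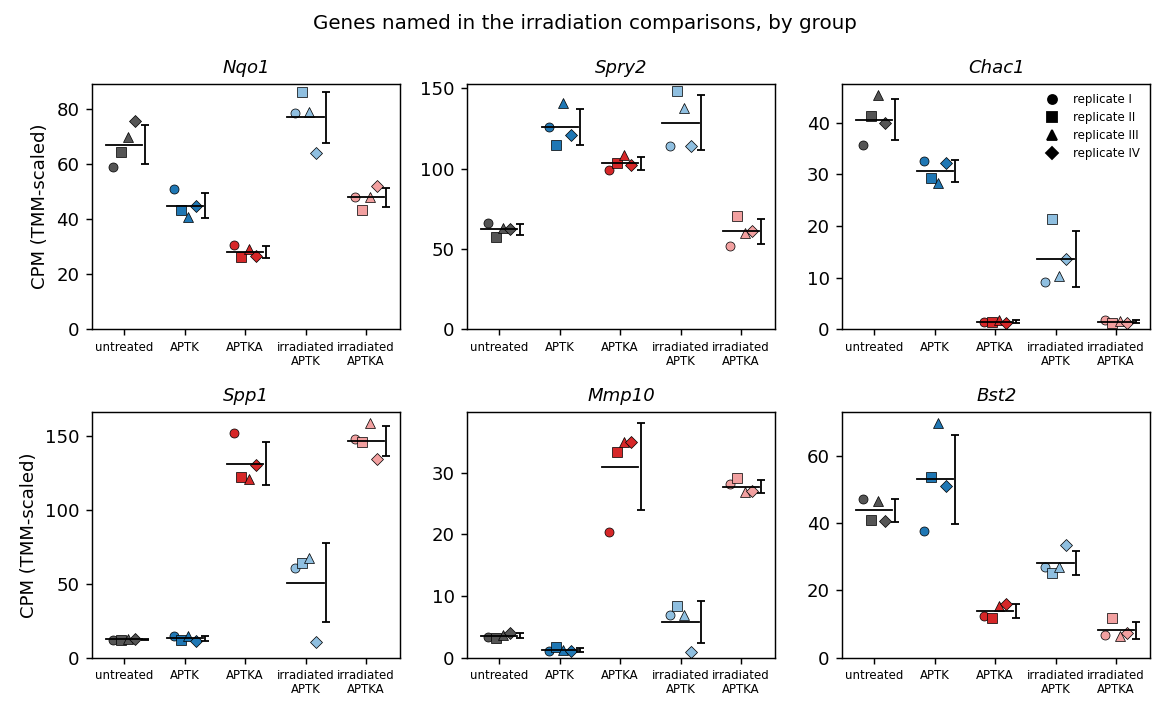
CPM of Nqo1, Spry2, Chac1, Spp1, Mmp10 and Bst2 in each of the 20 libraries by group on linear axes from 0, with a marker shape per replicate number, a line at the group mean and a bar of 1 SD. Nqo1 averages 47.9 CPM with irradiated APTKA medium against 28.2 CPM without irradiation, and Spp1 in irradiated APTK IV is at 10.6 CPM against 60.6 to 67.0 CPM in the other libraries of its group.

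The irradiated media were compared with each other to ask whether the difference between the organoid lines was also found in the irradiated arm. Stmn4 (6.75 ± 0.149), Il1rl1 (4.31 ± 0.113), Cxcl5 (4.02 ± 0.138), Atf3 (3.94 ± 0.305), Cxcl1 (3.88 ± 0.114) and Tnfaip3 (3.78 ± 0.0868) were higher with irradiated APTKA medium (log2 ± SE, n = 4 per group). Ackr4 (-5.37 ± 0.335), Iigp1 (-4.96 ± 0.415) and Mgp, an inhibitor of calcification (-4.83 ± 0.419), were lower. In total 9090 genes differed, 4468 higher and 4622 lower, 1681 at least 2-fold and 7452 called genes without overlap. More genes were higher than lower without a filter (4804 and 4323), with DESeq2 (4520 and 4484), without irradiated APTK II (4706 and 4463) and without irradiated APTK I and II (4475 and 4166). Ribosomal protein genes took 0.867 to 0.935% of counts with irradiated APTKA against 1.04 to 1.21% with irradiated APTK medium. Of the genes called here and between the plain media 3983 were higher and 3897 lower in both comparisons and 10 opposite, against 1389 and 1471 for independent lists, with r = 0.92 across genes.

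In the irradiated arm 19 of 25 inflammatory genes were higher and 2 lower, also over the list alone, and 18 of 20 NF-kB genes higher (camera, Up, adjusted p = 8.77e-15 and 1.59e-14). Of 30 p53 targets 23 were higher and 2 lower (Up, 7.13e-09). Stress response genes had 20 of 24 lower and 1 higher and chaperones 21 of 22 lower (Down, 8.77e-15 and 9.54e-13). These 5 lists also passed with an estimated correlation (adjusted p = 0.00115, 0.00280, 0.0400, 0.00348 and 0.00615). The p53 list lost this call without irradiated APTK II (0.0698), III (0.0583) or IV (0.0700). Interferon-stimulated genes had 27 of 29 lower and 1 higher, also over the list alone (Down, 3.81e-09; adjusted p = 0.385 with an estimated correlation), cholesterol genes 22 of 25 lower (Down, 3.10e-08; adjusted p = 0.235 with an estimated correlation) and collagens 22 lower and 3 higher of 28 (Down, 4.65e-05; adjusted p = 0.282 with an estimated correlation). Antigen presentation genes had 15 lower and 1 higher of 20 (Down, 0.00338; adjusted p = 0.282 with an estimated correlation) and MAPK feedback genes 12 lower and 7 higher of 22 (Down, 0.00494; adjusted p = 0.129 with an estimated correlation), both also over the list alone. The NRF2 list (0.0851) passed without irradiated APTKA IV (0.0495) or irradiated APTK IV (0.0183), though not with an estimated correlation (adjusted p = 0.724 and 0.532). Col1a1 was lower (-0.34), a call lost without irradiated APTKA IV (-0.28), irradiated APTK I (-0.31) or irradiated APTK IV (-0.26). Without irradiated APTK IV 8787 genes differed.

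The last comparison tested whether irradiation changed expression differently in APTKA than in APTK medium. Spry2 had a lower irradiation effect in APTKA medium, with a difference of -0.79 ± 0.121 on the log2 scale (SE, n = 4 per group; adjusted p = 0.00931). It went from 103.3 ± 3.95 to 60.9 ± 7.68 CPM in APTKA medium and from 125.7 ± 11.1 to 128.5 ± 17.1 CPM in APTK medium, where it did not pass (adjusted p = 0.913). Plk3, a stress-responsive kinase gene, also had a lower effect in APTKA medium (-0.79 ± 0.130) and Sesn2 a higher one (0.50 ± 0.0800). These 3 genes passed whichever library was left out. In all 27 genes differed, 18 with a higher and 9 with a lower effect in APTKA medium, and 1337 at an unadjusted p under 0.05. DESeq2 gave 114 genes and a fit without a filter 209. Without irradiated APTK IV the count was 307, including all 27. It was 4 without APTKA II, 10 without APTKA III, 6 without APTKA IV, 7 without APTK II and 7 without APTK IV. It was 5, 16 and 11 without irradiated APTKA I, II and III, and 43 and 10 without irradiated APTK II and III. Higher effects no longer outnumbered lower ones without APTKA II (2 and 2), APTKA IV (2 and 4), APTK IV (3 and 4), irradiated APTKA I (2 and 3), irradiated APTKA III (4 and 7) or irradiated APTK III (5 and 5).

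MAPK feedback genes had 3 of 22 with a lower irradiation effect in APTKA medium (9 over the list alone; camera, Down, adjusted p = 1.20e-16). Stress response genes had 2 of 24 with a higher effect (13 higher and 1 lower over the list alone; Up, 1.77e-15) and glycolysis genes 1 of 26 (12 over the list alone; Up, 5.05e-12). With an estimated correlation these passed at adjusted p = 0.000133, 0.00486 and 0.0349. The glycolysis list lost this call without APTKA I (0.0507), APTKA II (0.0571), APTK I (0.0673), APTK II (0.0572), irradiated APTKA IV (0.0550) or irradiated APTK IV (0.0991). Mitotic and DNA replication genes had 3 and 2 members with a lower effect over the lists alone (Down, 9.07e-13 and 6.48e-08; adjusted p = 0.0656 and 0.125 with an estimated correlation), and DNA replication passed without irradiated APTK IV (adjusted p = 0.0173 with an estimated correlation). Cholesterol genes had 1 of 25 with a higher effect (7 over the list alone; Up, 9.07e-13; adjusted p = 0.112 with an estimated correlation). The inflammatory list had 1 of 25 lower (9 lower and 2 higher over the list alone, camera adjusted p = 0.0679). It passed without APTKA IV (0.0488), APTK II (0.0468), irradiated APTKA III (0.0347) or irradiated APTK II (0.0478) or IV (0.0108). The run without irradiated APTK IV tested 27 members of this list. The interferon list did not pass (0.268), and passed without APTKA IV (0.00243), APTK I (0.000720) or irradiated APTK IV (0.0259). The NF-kB list (0.166) passed without APTKA IV (0.0295) or irradiated APTK II (0.0478). None of these 3 lists passed without those libraries with an estimated correlation (adjusted p = 0.121 to 0.714).

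In all 13 lists had a difference of irradiation effects with the preset correlation, 9 Up and 4 Down, where Up is a higher effect in APTKA medium. The other lists were collagens (Up, 1.87e-05), JAK-STAT3 targets (Up, 0.000538) and DNA repair genes (Down, 0.00120), each at adjusted p = 0.228 with an estimated correlation. Chaperones (Up, 0.00864; adjusted p = 0.277 with an estimated correlation) lost the call without irradiated APTK IV (0.129), and antigen presentation genes (Up, 0.0150; adjusted p = 0.303 with an estimated correlation) without APTK III (0.0719) or irradiated APTKA II (0.0980). NRF2 genes (Up, 0.0235; adjusted p = 0.566 with an estimated correlation) lost it without APTKA II (0.126), APTK I (0.134), irradiated APTKA IV (0.148) or irradiated APTK IV (0.477). Contractile genes (Up, 0.0361; adjusted p = 0.637 with an estimated correlation) lost it without APTKA II (0.123), APTK II (0.162) or IV (0.0910), irradiated APTKA III (0.0508) or IV (0.270), or irradiated APTK II (0.0847), III (0.104) or IV (0.121). Over the lists alone 2 JAK-STAT3 targets, 2 chaperones and 1 NRF2 gene had a higher effect in APTKA medium, and 0 collagens, DNA repair, antigen presentation or contractile genes passed.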

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

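The tests of a swapped library and of a wrong label or source were chosen after the position of irradiated APTK IV had been seen, and they were given 2 and 3 forms in turn. A library far from the other 3 of its group was found in 6 of 129 groups of values, where chance gives about 1 in 20, or 6.45. Cxcl1 was at 2.93 CPM in untreated II against 3.32 to 3.36 CPM in the others. Lif was at 24.7 CPM in APTKA I against 18.9 to 19.4 CPM, and Mdm2 at 191 CPM in APTK III against 203 to 205 CPM. Trib3 was at 114 CPM in untreated IV against 172 to 183 CPM. Spp1 was at 10.6 CPM in irradiated APTK IV against 60.6 to 67.0 CPM. On the line from the mean of plain APTKA libraries (0) to that of irradiated APTKA libraries (1), irradiated APTKA II lay at 0.570 against 0.675 to 0.695.

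Irradiated APTK IV lay at 0.193 on the line from the plain APTK mean (0) to the irradiated APTK mean (1), each without the library placed, while plain APTK libraries lay at 0.220 to 0.365 and irradiated APTK I to III at 0.569 to 0.702. A swap with an APTK library was argued against by position: none of the 4 lay beyond 0.365, and on lines drawn without replicate IV the highest, APTK I, lay at 0.283 against 0.461 to 0.518 for irradiated APTK I to III. Over genes called without the placed library and replicate IV, the median position was 0.212 for APTK I. It was 0.0144 to 0.0470 for the other plain libraries and 0.574 to 0.698 for irradiated APTK I to III. Exchanging APTK I with irradiated APTK IV gave 702 changed genes against 205 for the labelled groups, so a swap of these libraries is not excluded. Lower depth of the other libraries was also argued against: after thinning all libraries to 17.3 M counts, replicate IV lay at 0.220 and replicates I to III at 0.553 to 0.695. A wrong label, or a source that was not irradiated, cannot be told apart from a partial response: the first form of the test, its position of 0.193, allowed it, and the second argued against it on 1 list picked after its values were seen, the MAPK feedback genes, with a mean log2 CPM of 4.63 against 4.19 to 4.34 in plain APTK and 4.55 to 4.66 in irradiated APTK I to III. The third form took all 26 lists: set against each 3 plain APTK libraries, replicate IV lay beyond them, by more than their range and towards the irradiated libraries, in 3 to 8 lists, and a plain APTK library held out in the same way did so in 0 to 5, which keeps it open with 4 libraries per group.

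Irradiation effects differed between the media, by a test of the difference itself, for 27 genes and 13 of 26 lists, of which 3 lists also passed with an estimated correlation, 2 of them whichever library was left out. The 5 largest positive differences (APTKA minus APTK, log2) among genes at the naming rule's expression level were those of Adra1b (0.96), Aldh1a3 (0.86), Lrrc17 (0.81), Slc7a11 (0.74) and Nfil3 (0.60). Below that level, and named after their values were seen, Ccdc78 (1.81) and Gpr35 (1.57) had larger ones. The 5 largest negative differences at that level were those of Id1 (-1.03), Dusp6 (-1.01), Lif (-0.92), Gja1 (-0.81) and Spry2 (-0.79). Of these 10, Spry2 passed whichever library was left out, and Gja1 failed without APTKA II (-0.80). The other 8 each failed without any 1 of 7 to 13 libraries, in every case including APTKA II, without which the differences were 0.90 for Adra1b, 0.80 for Aldh1a3, 0.75 for Lrrc17, 0.75 for Slc7a11, 0.60 for Nfil3, -1.04 for Id1, -0.94 for Dusp6 and -0.95 for Lif.

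Other splits of the same libraries were tested for each count of changed genes. The labelled grouping gave more genes than any other split for APTKA medium against untreated (9096 genes, highest other split 0, 1 of 35 splits as large). The same held for APTK medium against untreated (6433, highest other 5, 1 of 35) and APTKA against APTK medium (9324, highest other 1, 1 of 35). It also held for irradiated against plain APTKA medium (108, highest other 11, 1 of 35) and the irradiated media (9090, highest other 50, 1 of 35). A share of 1 of 35 is the smallest that these splits can give. Other splits mix groups that differ, which raises the spread within each, so their low counts were largely fixed in advance. A batch or culture difference between groups cannot be judged from splits. For the difference of irradiation effects 3 of 100 splits drawn, the real one included, gave at least as many genes (27, highest other 45). These splits also remove any irradiation effect common to both media. They therefore do not test the difference alone, and chance cannot be excluded for it. Chance could also not be excluded for irradiated against plain APTK medium (205, highest other 702, 2 of 35). The split with 702 genes exchanged APTK I, the plain library nearest the irradiated ones, with irradiated APTK IV. Swapped labels of these libraries could also give this, and the cause was not tested. With APTK I kept in its group and irradiated APTK IV left out, 1271 genes differed.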

How the results depend on the processing

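The runs without the 2 libraries of lowest total and without 6 repeat-like loci, and list tests with an estimated correlation for left-out libraries, were chosen after seeing the data. Counts in the comparisons of media with untreated fibroblasts and with each other stayed within 1.5 times of their values under all settings run, and those with an irradiation contrast did not. Without a filter, irradiated against plain APTKA medium gave 316 genes, irradiated against plain APTK medium 492 and the difference of the effects 209. DESeq2 gave 307, 439 and 114. With only the compared groups in the fit, irradiated against plain APTKA medium gave 512 and irradiated against plain APTK medium 10. Without the 2 libraries of lowest total, irradiated against plain APTK medium gave 27. Leaving out each library in turn gave 34 to 146 genes for APTKA, 32 to 1271 for APTK and 4 to 307 for the difference. The cause was not tested. Over all comparisons 84 of 182 list tests passed with the preset correlation and 31 with an estimated one, of which 21 held whichever library was left out.

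Leaving out single libraries gave 8658 to 8757 genes for APTKA medium against untreated, 5799 to 6043 for APTK medium, 8873 to 9021 between the plain media and 8623 to 9169 between the irradiated media, and 81 to 88 lists. Of 11157 values of named genes under the alternatives 10561 kept their side of the threshold, 572 lost and 24 gained the call. With a call in either fit 0 values reversed, and direction was not compared where neither fit gave a call. Of 2574 list results 2399 kept their side, 111 lost and 64 gained the call, and 0 reversed by the same rule. Of 25 list calls gained without 1 library 0 passed with an estimated correlation. Upper quartile scaling put the median of all genes at -0.10 (log2) between the irradiated media. It gave 4354 higher and 4741 lower genes for APTKA and 3730 and 2898 for APTK medium against untreated, 3941 and 5471 between the plain media and 3789 and 5412 between the irradiated media, so which direction held more genes turned in the first 2.

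With the replicate number as a block the counts were 9027, 6345, 9277, 82, 178, 9031 and 22 in the order of the comparisons, and 85 lists. Deviations of libraries with the same number had correlations of -0.11 to 0.10, with 0 of 40 above 0.1, and 3 of 20 libraries matched their own number best. No shared deviation of same-numbered libraries was thus found, which does not show whether they came from 1 culture, animal or batch. At these depths simulated changes of 1.5-fold were recovered in 54% of genes for the difference of irradiation effects, in 68% for irradiated against plain APTKA medium and in 50% for irradiated against plain APTK medium. All simulated groups had the same spread per gene, so these shares may not hold for comparisons with the more variable irradiated APTK libraries. No simulation varied depth, so what depth limits was not tested.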

Other observations

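The test for immune cell reads was chosen after the interferon result had been seen. Single growth factor and niche genes changed with the media in both directions, and their lists did not pass camera. The genes given here are picked members of these lists. Bmp2, a bone morphogenetic protein gene, was at 6.16 ± 2.29 CPM with APTKA medium against 0.0693 ± 0.0360 CPM in untreated fibroblasts and 0.0692 CPM with APTK medium (log2 6.36 ± 0.430 over untreated; SD, n = 4). Igf1, a growth factor gene, fell from 118.9 ± 14.8 CPM to 15.2 ± 3.18 CPM with APTKA medium and was at 133.6 ± 12.5 CPM with APTK medium. Ptn, pleiotrophin, fell from 2401 ± 142 CPM to 343 ± 28.1 CPM with APTKA medium and was at 1425 ± 102 CPM with APTK medium. With APTK medium Fgf10, a growth factor for epithelium, rose from 23.3 ± 1.90 to 92.3 ± 7.92 CPM and Dkk2, a Wnt antagonist, by 1.66 on the log2 scale, while Rspo2, an R-spondin (-2.34), Nog, a BMP antagonist (-2.26), and Wnt2 (-2.07) fell.

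The pericyte markers Kcnj8, a potassium channel gene, and Abcc9 fell with APTKA medium: Kcnj8 went from 12.9 ± 0.656 to 1.38 ± 0.546 CPM and Abcc9, its sulfonylurea receptor partner, from 17.6 ± 1.32 to 2.39 ± 0.359 CPM. C3, the central complement component, rose by 4.49 ± 0.381 and C4b fell (-3.04 ± 0.502). The hedgehog target Gli1 fell (-2.44). Ccnd1, cyclin D1, rose by 1.01 with APTK medium.

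Of 29 interferon-stimulated genes 24 were higher with APTK medium than in untreated fibroblasts, 25 were lower and Cxcl10 higher with APTKA medium, and 28 were lower with APTKA than with APTK medium. These list calls were lost with an estimated correlation (adjusted p = 0.514, 0.698 and 0.366 with an estimated correlation). For reads from immune cells, 8 immune cell markers summed to at most 0.999 CPM in the APTK libraries, below the bound of 10. Preset immune markers outside that sum were higher. With APTK medium and in untreated, Lyz2 averaged 4.40 and 6.19 CPM, Cd68 1.70 and 1.42 and Cd14 1.56 and 1.27. Csf1r averaged 1.55 and 1.45 and Trac 8.30 and 7.66 CPM. The sum therefore argues against immune cell reads only for the 8 markers in it. A single library carrying the difference was also argued against, since at least 28 of 29 genes stayed lower with APTKA medium whichever of the 8 libraries was left out. A difference between the media in a factor that acts on interferon signalling may account for it, as a hypothesis that these data do not test.

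Gm10800 and Gm10801, loci that collect satellite-like reads, summed to 242 ± 61.3 CPM of unscaled totals with APTK medium against 25.1 ± 1.97 CPM in untreated fibroblasts (ratio 9.62). Olfactory and vomeronasal receptor genes, which sensory neurons express, had a ratio of 1.65, from 7.90 ± 0.688 to 13.1 ± 0.748 CPM of unscaled totals. The libraries did not overlap (7.22 to 8.79 and 12.4 to 14.1 CPM), so some added genomic DNA is not excluded. With APTKA medium the receptor genes were at 12.3 ± 0.529 CPM, while the satellite-like loci summed to 50.4 ± 21.1 CPM. Genomic DNA as the source of the whole rise of these loci with APTK medium was therefore argued against. Satellite transcription and reads shared between repeat copies stay open and were not tested.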
